A study of Rattus norvegicus with 50 samples.

How the data were processed

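Kidney cortex and kidney medulla of ZSF1 rats were profiled by stranded total RNA sequencing after removal of ribosomal RNA. Per the labels' protocols, kidneys were flash frozen and RNA was extracted with a Qiagen kit. Per the same protocols, 1 µg of total RNA entered each Illumina stranded library. There were 10 groups of 5 libraries, formed by 2 tissues and 5 treatments, 50 libraries in all. Lean rats received vehicle. Obese rats received vehicle, enalapril at 10 mpk, or MK-8722 at 1 or 10 mpk, in the dose unit of the labels. The labels give a treatment time of 28 weeks beside an age of 20 weeks, so the age may refer to another time point and was not used. Nothing in the labels says which libraries came from the same animal, so p-values measure the spread between these libraries.

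The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 32545 Ensembl gene IDs, per the file headers. The aligner, the counting tool and the genome build are not given in the sources used here. Each column was matched to its sample by the library number in the sample's description. The table pairs IDs with no gene names, and 0 of the IDs matched the Ensembl column of the reference gene table. Genes are therefore reported by ID and no name was inferred. The 40 gene lists fixed before the data were examined, and their set tests, could not be run without names.

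FPKM are not counts, so tests were run on log2(FPKM + 0.5), and every log2 fold change below is on that scale, which understates changes of low genes. Genes with an FPKM of at least 1 in 5 or more libraries of a fit were tested. R 4.3.3 with limma 3.58.1 was used, with a mean-variance trend and robust moderation. Each tissue was fitted on its 25 libraries with a mean per group. A joint fit of all 50 libraries gave the tissue difference in lean rats and the interactions of tissue with genotype or treatment. Calls had a two-sided Benjamini-Hochberg adjusted p under 0.05 over all tested genes of the comparison.

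The fixed rule for naming genes took the largest rises and falls past the threshold, with a mean FPKM of at least 2 in the higher group and no overlap between the 5 values of each group. That rule also asked for a gene symbol. Because no symbols were at hand, it was applied without that condition and restricted to 2 IDs per direction, in the comparisons against lean vehicle and against obese vehicle only.

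Absolute sequencing depth is unknown. In genes detected in 5 to 22 libraries, low values fell on whole multiples of the value of 1 read. With a tolerance of 0.1 reads, 94.3% of 57161 values in 4813 genes did so, which gave the relative depth of each library. Relative depth ranged from 0.599 to 1.53 and limits the precision of low genes.

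A position between lean and obese was defined after the data had been seen. It projects each library on the line from the lean mean, set to 0, to the mean of the obese MK-8722 1 mpk group, set to 1. The libraries of obese vehicle, enalapril and MK-8722 10 mpk thus take no part in defining the line. Groups were compared with exact two-sided permutation tests, adjusted over 6 tests; with 5 against 5 libraries the smallest p is 0.00794.

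Replicate numbers recur across groups, and it was checked whether libraries with the same number deviate together from their group means. All 3 same-numbered library pairs of cortex MK-8722 10 mpk and obese vehicle correlated, with r of 0.24 to 0.41 across genes. These numbers were therefore treated as a possible pairing, although the labels state none and genes are not independent replicates. Of the 3 libraries with a partner, 2 correlated best with their own number. Adding the number as a block gave 3970 calls there. No other comparison met the rule that every pair exceed r = 0.1. Same-numbered cortex and medulla libraries of MK-8722 10 mpk lay at its edge, with r of 0.1 to 0.31.

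Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, rescaling of each library by its median ratio to the gene-wise geometric mean, a fit of the 2 compared groups alone, the replicate number as a block, leaving out each library in turn, and, for overlaps that share the obese vehicle libraries, a split of those libraries between the 2 comparisons. Relative depth as a term, the range of library numbers as a term, and leaving out 8 cortex libraries with numbers in a separate higher range were chosen after the data had been seen. The procedures were tested on simulated data with known changes. In the simulated cortex comparison of MK-8722 1 mpk with obese vehicle over 13579 genes, 50% of 66 genes with a log2 change of 0.5 were recovered, as were 92.5% of 67 with a change of 1. In the simulated medulla comparison over 14195 genes these shares were 53% of 66 and 86.6% of 67. The simulated noise was independent between genes and had no shifts shared across a library. These shares are therefore not the power in the real libraries.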

Results

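The series asks how activation of AMP-activated protein kinase by MK-8722, given at 2 doses, changes the kidney of the obese ZSF1 rat, a model of progressive diabetic kidney disease. Enalapril, an inhibitor of angiotensin-converting enzyme, served as the comparator. Cortex and medulla were each measured in 5 libraries of lean vehicle, obese vehicle, obese enalapril 10 mpk, obese MK-8722 1 mpk and obese MK-8722 10 mpk rats. The 6 most abundant gene IDs held 39.1% to 66.2% of the summed FPKM of a library. Their share was 61.2% ± 2.37 in lean and 52.6% ± 8.23 in obese vehicle cortex, and 61.9% ± 1.43 and 54.0% ± 1.23 in medulla (SD, n = 5). Relative depth was also higher in lean than in obese vehicle libraries, at 1.36 ± 0.081 and 1.02 ± 0.212 in cortex and 1.13 ± 0.0774 and 0.728 ± 0.0816 in medulla (SD, n = 5).

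Large changes with obesity were measured in cortex. On the deposited values, of 13579 genes tested, 7373 were higher and 927 lower in obese vehicle than in lean vehicle rats (limma, adjusted p under 0.05). ENSRNOG00000043451 rose from 48.7 ± 5.87 to 3198 ± 1310 FPKM (SD, n = 5), a log2 fold change of 5.91 ± 0.334 (SE, adjusted p = 4.31e-11). ENSRNOG00000030729 rose from 2.75 ± 0.675 to 114 ± 27.8 FPKM, a log2 fold change of 5.12 ± 0.292 (adjusted p = 4.86e-11). ENSRNOG00000010932 fell from 9.33 ± 0.868 to 0.839 ± 0.386 FPKM, with a log2 fold change of -2.92 ± 0.187 (adjusted p = 4.86e-11), and ENSRNOG00000036984 fell from 7.98 ± 3.2 to 1.02 ± 0.97 FPKM (log2 fold change -2.63, adjusted p = 0.00024). The deposited values of the 2 groups did not overlap for 40.8% of genes, against 0.794% by chance. A shift shared by the genes of a library can add to this share, which was not computed after rescaling.

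The balance of rises and falls in cortex depended on the scaling. The median log2 fold change over all genes was 0.30 as deposited. After median-ratio rescaling, which sets that median near 0, 3184 genes were higher and 3028 lower, and all 3184 of these rises were also called on the deposited values. All 927 deposited falls were kept as well, while 59 deposited rises became falls. ENSRNOG00000043451 had a log2 fold change of 5.56 after rescaling. With relative depth as a term, added after the data were seen, 4581 genes were called. In the libraries of the lower number range alone 7838 genes were called, and with the range as a term 8175.

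Medulla showed the same picture. Here 8060 genes were higher and 1551 lower in obese vehicle rats among 14195 tested, and 3823 and 3761 after rescaling, which removed a median log2 fold change of 0.37. ENSRNOG00000013973 rose from 2.99 ± 0.898 to 114 ± 35.1 FPKM (SD, n = 5; log2 fold change 5.04 ± 0.281 SE, adjusted p = 2.81e-12). ENSRNOG00000048402 rose from 0.483 ± 0.234 to 64.8 ± 60 FPKM (log2 fold change 5.46, adjusted p = 1.24e-08). ENSRNOG00000019481 fell from 27.5 ± 5.39 to 0.807 ± 0.821 FPKM and ENSRNOG00000002602 from 23.8 ± 1.45 to 1.07 ± 0.593 FPKM, with log2 fold changes of -4.61 (adjusted p = 1.49e-11) and -4.06 (adjusted p = 1.93e-09). With relative depth as a term 5451 genes were called.

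Changes with obesity were largely shared between the tissues. Among 13373 genes tested in both, 6259 were higher in both and 686 lower in both, where independent lists would give 4207.3 and 95.8, and 48 moved in opposite directions. Log2 fold changes correlated across genes with r = 0.856 (Spearman 0.815); genes are not independent replicates. After rescaling, 2539 were higher in both and 2355 lower in both. The interaction of genotype with tissue was nevertheless called for 709 of 14586 genes, 428 with a more positive effect in cortex and 281 in medulla, or 950 genes after rescaling. The count was 446 without medulla obese vehicle replicate 7, and without cortex obese vehicle replicate 2 the directions were near even, at 325 and 332. Calls that held in the same direction in every alternative fixed beforehand numbered 189, 96 more positive in cortex and 93 in medulla. In lean rats 1681 genes were higher and 4145 lower in cortex than in medulla, and 2690 and 2908 after rescaling.

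**Figure D1:**
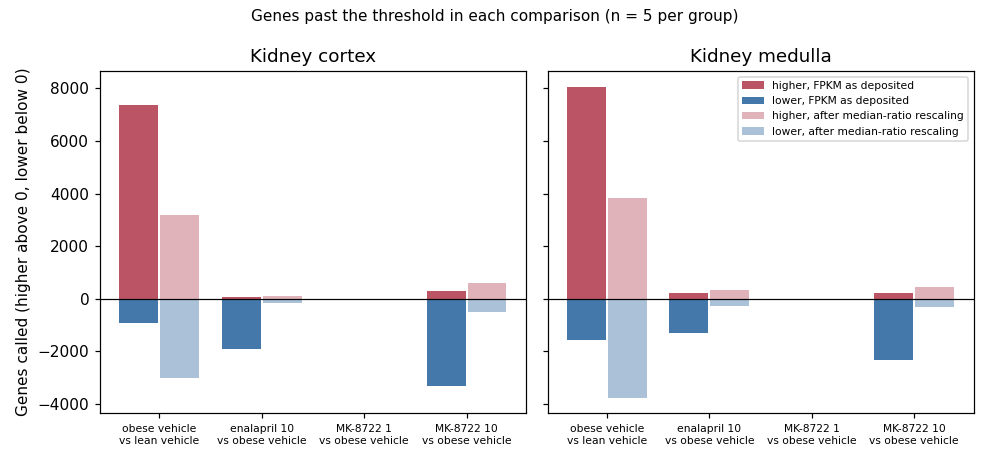
Number of genes called higher (above 0) or lower (below 0) in each comparison (x axis), for cortex and medulla, with 5 libraries per group. Dark bars use FPKM as deposited and light bars the values after median-ratio rescaling; in cortex, for example, 7373 rises with obesity became 3184 after rescaling, and MK-8722 at 1 mpk had 0 calls.

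On the deposited values, 4 genes in cortex and 21 in medulla were called at least 2-fold higher with enalapril than with obese vehicle. ENSRNOG00000002937 rose from 6.59 ± 1.02 to 48.2 ± 13.4 FPKM in cortex (SD, n = 5; log2 fold change 2.75 ± 0.485 SE, adjusted p = 0.00992). In medulla it rose from 1.66 ± 0.571 to 15.1 ± 7.45 FPKM (log2 fold change 2.71 ± 0.477 SE, adjusted p = 0.0127). ENSRNOG00000013062 rose by 1.47 on the log2 scale in cortex, from 80.5 ± 26.3 to 226 ± 77.9 FPKM (adjusted p = 0.0196). ENSRNOG00000025571 and ENSRNOG00000007778 fell in cortex, with log2 fold changes of -1.66 (adjusted p = 0.0196) and -1.43 (adjusted p = 0.0201). In medulla, ENSRNOG00000003288 rose by 1.58 (adjusted p = 0.038), while ENSRNOG00000007552 and ENSRNOG00000014714 fell with log2 fold changes of -1.73 (adjusted p = 0.0131) and -1.62 (adjusted p = 0.0158). With relative depth as a term the 4 cortex calls named here were lost (adjusted p = 0.122, 0.223, 0.245 and 0.245), while their log2 fold changes were 2.48 for ENSRNOG00000002937, 1.47 for ENSRNOG00000013062, -1.25 for ENSRNOG00000025571 and -1.28 for ENSRNOG00000007778. Those of ENSRNOG00000013062, ENSRNOG00000025571 and ENSRNOG00000007778 in cortex were also lost without enalapril replicate 4 or obese vehicle replicate 1, 2 or 6 (adjusted p of 0.0507 to 0.0807). In medulla, ENSRNOG00000002937 and ENSRNOG00000007552 were lost without obese vehicle replicate 7 (both adjusted p = 0.064), and ENSRNOG00000014714 without that library (0.0734) or enalapril replicate 5 (0.0555). ENSRNOG00000003288 missed the threshold without enalapril replicate 2, 5, 6 or 7 or obese vehicle replicate 4 or 6 (adjusted p of 0.0586 to 0.0958), and without obese vehicle replicate 7 its log2 fold change was 1.03 (adjusted p = 0.12). It also missed the threshold without the filter (adjusted p = 0.0526) and with only the 2 groups fitted (0.108).

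With the IDs named above included, enalapril gave 65 higher and 1894 lower genes in cortex and 223 higher and 1286 lower in medulla. The median log2 fold change over all genes was -0.17 in cortex and -0.14 in medulla. Rescaling left 96 higher and 172 lower in cortex and 322 and 260 in medulla. Single libraries decided these counts. In cortex the count of 1959 became 23, 33 and 34 without obese vehicle replicates 2, 1 and 6 and 43, 267, 415 and 596 without enalapril replicates 4, 7, 6 and 2. It became 4531 without obese vehicle replicate 5, the only obese vehicle library of the higher number range. In medulla the count of 1509 became 7, 377 and 519 without obese vehicle replicates 7, 6 and 4, and 27, 664 and 901 without enalapril replicates 5, 7 and 2. It became 2345 without enalapril replicate 3. Calls that held in the same direction whichever library was left out numbered 21 in cortex, 4 of them higher, and 7 in medulla, 1 of them higher. With relative depth as a term cortex had 1 call and medulla 1325. Without the filter the counts were 820 and 755, and with only the 2 groups fitted 312 and 973. In the lower number range cortex had 3778 calls, and 2500 with the range as a term.

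MK-8722 at 1 mpk gave no call in either tissue. At an unadjusted p under 0.05, limma found 583 genes in cortex and 577 in medulla, fewer than the 679 and 710 that chance would give. The smallest adjusted p was 0.509 in cortex. In medulla 1 gene was called without MK-8722 1 mpk replicate 7. The standard error of a gene's log2 fold change had a median of 0.123 in cortex and 0.131 in medulla, which is not a limit of detection. Even in simulated data with independent noise, only 50% of genes with a log2 change of 0.5 were recovered in cortex and 53% in medulla. Changes of that size in single genes were therefore not excluded.

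MK-8722 at 10 mpk raised ENSRNOG00000006873 in cortex from 52.5 ± 11.9 to 347 ± 80 FPKM (SD, n = 5; log2 fold change 2.71 ± 0.18 SE, adjusted p = 5.97e-10). In medulla the same ID rose from 58.9 ± 30.2 to 207 ± 61.2 FPKM (log2 fold change 1.95 ± 0.329 SE, adjusted p = 0.00117). ENSRNOG00000011269 rose in cortex from 0.289 ± 0.124 to 5.09 ± 0.471 FPKM (log2 fold change 2.83, adjusted p = 5.09e-10). ENSRNOG00000010932, which fell with obesity, rose from 8.46 ± 3.89 to 27.3 ± 6.48 FPKM in medulla (adjusted p = 0.000854), where lean rats had 23.1 ± 2.21. In cortex it rose from 0.839 ± 0.386 to 5.46 ± 1.21 FPKM (adjusted p = 3.32e-08), against 9.33 ± 0.868 in lean rats. Falls were led in cortex by ENSRNOG00000009589 (log2 fold change -2.63, adjusted p = 8.08e-05) and ENSRNOG00000037118 (-2.40, adjusted p = 0.00289). In medulla they were led by ENSRNOG00000013062 (-2.39, adjusted p = 3.84e-06) and ENSRNOG00000031641 (-1.88, adjusted p = 0.0112). The cortex fall of ENSRNOG00000037118 missed the threshold with relative depth as a term (log2 fold change -1.95, adjusted p = 0.101), or with depth and the pairing together (-2.02, adjusted p = 0.272). That of ENSRNOG00000031641 in medulla did so with only the 2 groups fitted (adjusted p = 0.0508).

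The counts were 288 higher and 3327 lower in cortex and 227 higher and 2345 lower in medulla. The median log2 fold change over all genes was -0.19 in cortex and -0.18 in medulla. After rescaling they were 586 and 511 in cortex and 443 and 305 in medulla. In both tissues together, 84 genes were higher and 1195 lower on the deposited values, where independent lists would give 4 and 570, and 9 were opposite. After rescaling, 175 were higher and 91 lower in both, where independent lists would give 17.2 and 11.1, and 3 were opposite. Calls that held whichever library was left out numbered 1577 in cortex and 899 in medulla. The cortex count of 3615 became 1784, 2383 and 2397 without obese vehicle replicates 2, 1 and 6 and 1869 without MK-8722 10 mpk replicate 5. The medulla count of 2572 became 1030, 1607 and 1707 without obese vehicle replicates 7, 6 and 4 and 1259 and 1388 without MK-8722 10 mpk replicates 5 and 1. In cortex, 3 of the 5 libraries at 10 mpk and 1 of the 5 obese vehicle libraries had numbers in the higher range. With that range as a term 2183 genes were called, and 977 in the lower range alone; the higher range holds too few libraries for a value. Relative depth as a term gave 431 calls in cortex, or 244 with the pairing kept in the fit, and 851 in medulla, and a fit of the 2 groups alone 480 and 465.

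**Figure D2:**
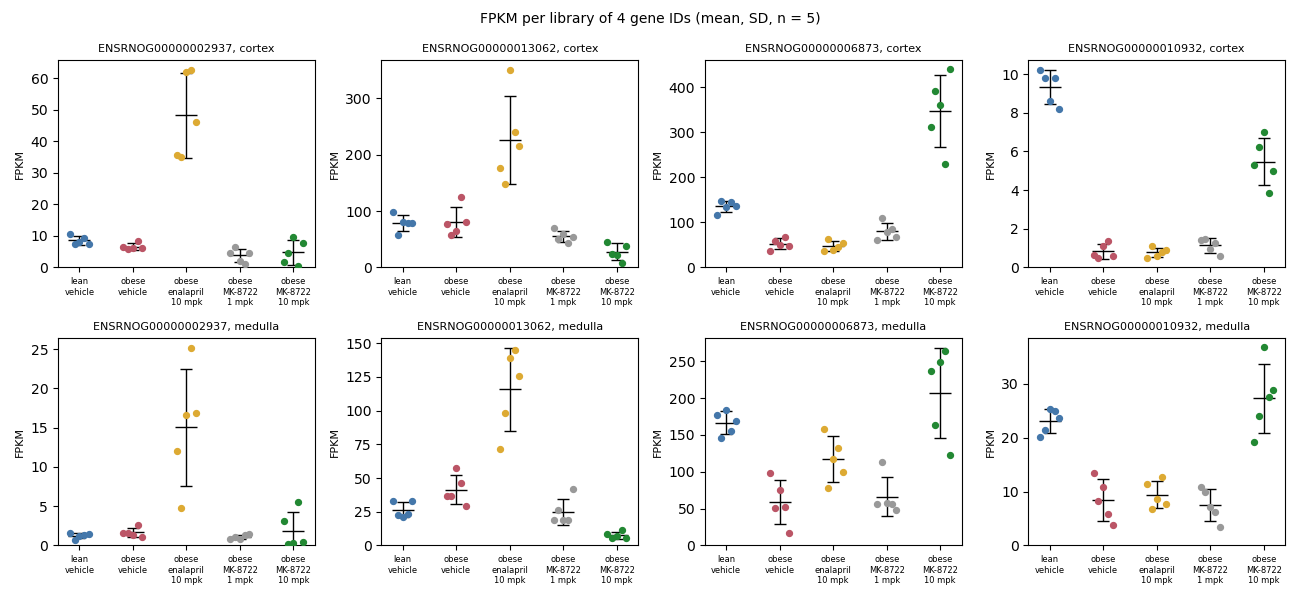
FPKM (y axis) of 4 gene IDs in every library of the 5 groups (x axis), in cortex (upper row) and medulla (lower row); points are libraries and bars the mean and SD of 5. ENSRNOG00000002937 stood at 48.2 ± 13.4 FPKM with enalapril against 6.59 ± 1.02 in obese vehicle cortex, and ENSRNOG00000006873 at 347 ± 80 with MK-8722 10 mpk.

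The direct comparison of the doses of MK-8722 gave calls in both tissues, with counts that varied widely. In cortex 304 genes were higher and 3802 lower at 10 than at 1 mpk, and in medulla 145 higher and 695 lower. Rescaling gave 696 and 628 in cortex and 240 and 160 in medulla. ENSRNOG00000010932 was higher at 10 mpk in cortex by a log2 fold change of 1.87 (adjusted p = 9.57e-07) and in medulla by 1.85 (adjusted p = 0.000872). The cortex count of 4106 became 454 in the lower number range, 2353 with the range as a term and 326 with relative depth as a term. It became 2696 and 2625 without MK-8722 1 mpk replicates 1 and 4 and 1748 without MK-8722 10 mpk replicate 5. The medulla count of 840 became 314, 158 and 367 without MK-8722 1 mpk replicates 4, 6 and 7, and 226, 1385, 430, 150 and 1593 without MK-8722 10 mpk replicates 1, 2, 3, 5 and 6. It was 72 with only the 2 groups fitted (1966 in cortex), 401 without the filter and 455 with relative depth as a term.

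Called against obese vehicle, 888 genes were lower with both MK-8722 10 mpk and enalapril in cortex and 774 in medulla, 7 and 38 were higher with both, and 31 and 6 were opposite. Independent lists would give 464.1 and 212.4 lower with both, and single libraries decided the enalapril counts behind these lists. After rescaling, 36 and 88 were lower with both, 14 and 84 higher with both, and 15 and 3 opposite. ENSRNOG00000013062 rose with enalapril and fell with MK-8722 10 mpk in cortex (log2 fold change -1.66, adjusted p = 0.00131) and in medulla, and between the drugs it differed by -3.13 in cortex (adjusted p = 1.19e-06) and -3.85 in medulla (adjusted p = 6.75e-10). ENSRNOG00000002937 was lower with MK-8722 10 mpk than with enalapril by a log2 fold change of -3.63 in cortex (adjusted p = 3.32e-05) and -3.12 in medulla (adjusted p = 0.000802). ENSRNOG00000006873 was higher with MK-8722 10 mpk by 2.86 in cortex (adjusted p = 1.77e-10), whereas in medulla the difference of 0.81 did not pass (adjusted p = 0.228). In the direct comparison the drugs differed for 520 genes higher and 788 lower with MK-8722 10 mpk in cortex, and for 116 higher and 272 lower in medulla. Rescaling gave 720 and 729 in cortex and 181 and 103 in medulla. In the lower number range the cortex count was 230, and with the range as a term 1146; a fit of the 2 groups alone gave 796 in cortex and 48 in medulla. The medulla count of 388 became 609, 137, 199 and 158 without enalapril replicates 3, 5, 6 and 7, and 591, 136 and 149 without MK-8722 10 mpk replicates 1, 2 and 3, and was 256 without the filter.

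The overlap between the drugs shares the obese vehicle libraries, and was checked for this after the data were seen. Log2 fold changes of the drugs correlated across genes with r = 0.463 in cortex and 0.578 in medulla, where simulated groups without an effect gave 0.523 and 0.535. The covariance was 0.034 and 0.0469, against 0.0153 and 0.0208 without an effect. When the obese vehicle libraries were split between the drugs, the median over 20 splits was 0 genes lower with both in cortex (0 to 205, limma) and 1 in medulla (0 to 102), with r of 0.201 and 0.306. Each drug was then compared with fewer obese vehicle libraries, so these counts do not separate the sharing from the loss of libraries.

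Of the 7373 genes raised in obese cortex, 1828 fell with enalapril and 2457 with MK-8722 10 mpk. Of the 927 lowered, 44 rose with enalapril and 130 with MK-8722 10 mpk, whereas 3 and 108 fell further. After rescaling, of 3028 lowered genes 84 rose with enalapril and 346 with MK-8722 10 mpk, whereas 0 and 47 fell further. On the deposited values, 1872 calls were opposite for enalapril and 2587 for MK-8722 10 mpk in cortex. In medulla the counts were 1473 and 2307. Independent lists would give 1033, 1826, 755 and 1356 on the deposited values. After rescaling the opposite calls numbered 251, 649, 564 and 626, each more than independent lists would give on that scale. MK-8722 at 1 mpk had 0 opposite calls in either tissue. A further 762 genes that were not called with obesity in cortex fell with MK-8722 10 mpk, or 161 after rescaling. The cortex count of 1872 for enalapril became 29, 18, 4322 and 30 without obese vehicle replicates 1, 2, 5 and 6, and 558, 38, 395 and 253 without enalapril replicates 2, 4, 6 and 7. That of 2587 for MK-8722 10 mpk became 1530, 1091, 4091 and 1522 without the same obese vehicle libraries and 1230 without MK-8722 10 mpk replicate 5. In medulla the count of 1473 became 506, 364 and 5 without obese vehicle replicates 4, 6 and 7, and 877, 2273, 23 and 644 without enalapril replicates 2, 3, 5 and 7. That of 2307 became 1534, 1436 and 904 without the same obese vehicle libraries and 1179 and 1084 without MK-8722 10 mpk replicates 1 and 5.

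These overlaps share the obese vehicle libraries. Over all genes, in a check chosen after the data were seen, log2 fold changes with obesity and with treatment had opposite signs for 87.1% with enalapril and 79.2% with MK-8722 10 mpk in cortex, and for 87.3% and 82.2% in medulla. Simulated groups without an effect gave 69.5% and 69.6% in cortex and 65.4% and 66.9% in medulla. After rescaling the observed shares were 80.7% and 65.5% in cortex and 81.8% and 74.3% in medulla. The share of 65.5% for MK-8722 10 mpk lay below the 69.6% without an effect, which was simulated on the deposited scale. The simulated groups gave 0 opposite calls in the median of 30 draws, which is no measure of overlap where there are real effects, with correlations between the log2 fold changes of -0.502 for enalapril and -0.526 for MK-8722 10 mpk in cortex and -0.488 and -0.515 in medulla. Observed correlations across genes were -0.752 and -0.451 in cortex and -0.776 and -0.602 in medulla. The observed covariance was -0.114 for enalapril and -0.0741 for MK-8722 10 mpk in cortex, against -0.0161 and -0.0156 without an effect, and -0.159 and -0.119 in medulla, against -0.0193 and -0.0198. When the obese vehicle libraries were split between the comparisons, the median count over 20 splits fell to 0.5 for enalapril and 831 for MK-8722 10 mpk in cortex and to 2 and 512.5 in medulla. These splits ranged from 0 to 3279 and 121 to 2775 in cortex, and from 0 to 2395 and 17 to 2433 in medulla. Each comparison then had fewer obese vehicle libraries, which alone can lower such counts. The cortex count of 1872 for enalapril became 18 without obese vehicle replicate 2. The lower counts therefore do not separate the sharing from the loss of libraries. The correlations stayed negative at the median, at -0.573 and -0.338 in cortex and -0.638 and -0.479 in medulla.

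On the line from lean (0) to obese MK-8722 1 mpk (1), which was chosen after the data were seen, enalapril libraries lay nearer to lean than obese vehicle libraries. Their positions were 0.553 ± 0.097 and 0.884 ± 0.21 in cortex (SD, n = 5; exact permutation p = 0.0159, adjusted 0.0477) and 0.692 ± 0.079 and 0.994 ± 0.14 in medulla (exact permutation p = 0.00794, the smallest possible, adjusted 0.0476). In the lower number range the cortex difference was -0.395, with an exact adjusted p of 0.0858. With the libraries left there the exact test could give no smaller unadjusted p, so it cannot tell whether the difference holds in that range. Over both number ranges, the cortex difference missed the threshold without enalapril replicate 2, 4, 6 or 7 (exact adjusted p = 0.0951 each) or obese vehicle replicate 1, 2, 3 or 6 (0.0714 each). MK-8722 10 mpk libraries lay at 0.651 ± 0.23 in cortex and 0.736 ± 0.21 in medulla, and their difference from obese vehicle did not pass (exact p = 0.111, adjusted 0.166, and exact p = 0.0556, adjusted 0.111). In cortex the difference was -0.268 in the lower number range. The same-numbered cortex pairs were compared after their positions were seen. All 3 lay lower with MK-8722 10 mpk, by -0.213, -0.191 and -0.0905, but after rescaling 2 of 3 did (-0.0968, -0.117 and 0.006). A permutation that kept the pairs and redrew the unpaired libraries gave an exact p of 0.0417, the smallest of its 48 relabellings (adjusted 0.0834). After rescaling this permutation gave an exact p of 0.0833 (adjusted 0.125). Sign flips of the 3 pairs alone gave an exact p of 0.25, the smallest that 3 pairs allow, and 0.5 after rescaling. The difference between MK-8722 10 mpk and enalapril on this line did not pass, at 0.0975 in cortex (exact p = 0.365, adjusted 0.438; 0.0258 to 0.164 leaving out single libraries) and 0.044 in medulla (exact p = 0.69, adjusted 0.69; -0.00411 to 0.107), so a difference was not excluded.

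**Figure D3:**
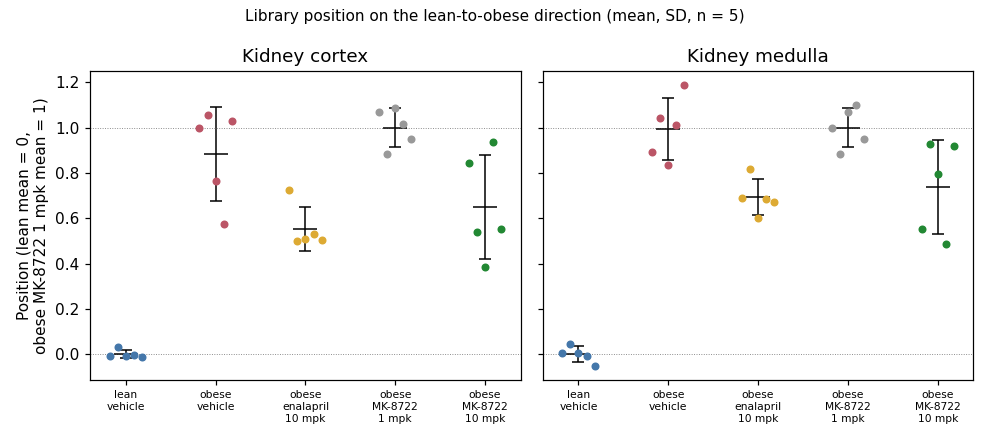
Position of each library (y axis, no unit) between the lean mean (0) and the mean of obese MK-8722 1 mpk (1), by group (x axis), in cortex and medulla; points are libraries and bars the mean and SD of 5. Lean and MK-8722 1 mpk means are fixed at 0 and 1; enalapril stood at 0.553 ± 0.097 in cortex and 0.692 ± 0.079 in medulla.

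Few differences of treatment effects between the tissues passed the test. The interaction with tissue was called for 1 gene with enalapril, 0 with MK-8722 1 mpk (400 at an unadjusted p under 0.05 by limma, 729 expected) and 33 with MK-8722 10 mpk, 16 of them more positive in cortex. ENSRNOG00000060193, named after its value was seen, was the gene with enalapril (log2 difference -1.48 ± 0.268 SE, adjusted p = 0.0225). No gene was called by limma for enalapril without cortex enalapril replicate 1 or 7, cortex obese vehicle replicate 1, 2 or 6, medulla enalapril replicate 5, 6 or 7 or medulla obese vehicle replicate 6 (774 at an unadjusted p under 0.05 with all libraries), and 2 were called without cortex obese vehicle replicate 3 or 5. For MK-8722 10 mpk, ENSRNOG00000011269 rose more in cortex (log2 difference 2.17, adjusted p = 1.21e-05). This ID did not pass the expression filter of the medulla fit. The count of 33 became 18 without medulla obese vehicle replicate 7 and 59 without cortex MK-8722 10 mpk replicate 2. Of the 33 calls, 4 held in the same direction in every alternative fixed beforehand.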

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

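The counts over other splits of the libraries were set out before their results were seen. The tests on abundant genes, depth, shared vehicle libraries, number range, scaling and the medulla shift of cortex calls, the splits after removal of a common effect, the tallies of splits by range or by pairs, and the positions with the pairs kept, were chosen only after the result they bear on, or a closely related value, had been seen.

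Relabelling the libraries of the 2 groups gave 100 splits per comparison, the real one included. The shares below are not adjusted over the comparisons, so they cannot exclude chance. They argue against it where fewer than 5 of the 100 splits, the real one included, reached the real count. For obesity 1 split did so, with 8300 calls in cortex against at most 6222 in another split and 9611 in medulla against 5882. For enalapril it was 1 split, with 1959 against 1403 in cortex and 1509 against 1078 in medulla, as for its opposite calls (1872 against 617, and 1473 against 1045). For MK-8722 10 mpk in medulla it was 1 split (2572 against 1784), as for its opposite calls (2307 against 1712). Between doses it was 1 split in cortex (4106 against 3657) and 2 in medulla (840 against 1001). Between the drugs in cortex it was 1 split (1308 against 219), as for the lean tissues (5826 against 2895).

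By this rule chance stays open for the count of calls with MK-8722 10 mpk in cortex, where 5 of 100 splits gave as many (3615, highest other 5993). It also stays open for the count between the drugs in medulla, with 5 splits (388, highest other 1604). These splits counted calls on the deposited values and do not test single genes. Of the 3615 cortex calls, 347 held in the same direction in every alternative fixed beforehand, as did 43 of the 388. The highest other count was several times the real one between the drugs in medulla, and for the interaction of MK-8722 10 mpk after removal of the common effect (1459 against 33), which may reflect a structure of these libraries; no test identified one. In cortex 55 of the 100 splits of MK-8722 10 mpk and obese vehicle divided the 4 libraries of the higher number range unevenly, as the real one does. Of these, 39 gave 0 calls (limma) and 5, the real one included, gave as many as the real one, while the highest of the 45 even splits was 1124. In the lower range alone 977 genes were called, and 2183 with the range as a term. For the opposite calls in cortex 2 of 100 splits reached the real count (2587, highest other 4803), without regard to the pairs. The 19 splits that parted as many same-numbered pairs as the real one are too few for a share under 0.05; the highest other among them was 0 for the calls and 0 for the opposite calls. For MK-8722 1 mpk the real count of 0 was reached by 100 splits in each tissue (highest other 133 in cortex and 1 in medulla), as were its opposite calls (16 and 1) and its interaction (7). Every split reaches a count of 0, so these splits cannot decide anything for MK-8722 1 mpk. For the other interactions 8, 8 and 10 splits reached the real counts for obesity (709, highest other 8676), enalapril (1, 1774) and MK-8722 10 mpk (33, 1300). Splitting the tissues independently turns an effect shared by them into an interaction. The common effect, estimated from the real labels, was then removed. The numbers became 1 for obesity (707, highest other 166), 5 for enalapril (1, 1) and 3 for MK-8722 10 mpk (33, 1459). This argues against chance for obesity and not for enalapril. For MK-8722 10 mpk 3 is under 5, but another split gave 1459 calls. The splits also took no regard of the same-numbered libraries, so chance stays open there.

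In 84 sets of 5 libraries, 8 had a library far from the others, where about 4.2 would by chance. Cortex enalapril replicate 1 stood at position 0.726, the others between 0.498 and 0.529. Medulla lean replicate 1 had a relative depth of 0.992, the others at least 1.14. In cortex, ENSRNOG00000002937 was at 8.36 FPKM in obese vehicle replicate 5, ENSRNOG00000025571 at 1.61 in enalapril replicate 2, and ENSRNOG00000037118 at 1.54 in MK-8722 10 mpk replicate 6, where the others were at most 0.004. In medulla, ENSRNOG00000007552 was listed at 0 in enalapril replicate 2, ENSRNOG00000014714 was at 7.24 in enalapril replicate 3, and ENSRNOG00000031641 at 43.3 in obese vehicle replicate 5.

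The interaction of effect and tissue was called for 709 genes with obesity, 33 with MK-8722 10 mpk and 1 with enalapril. For both drugs chance stays open. With obesity the log2 effect in cortex minus that in medulla was 1.503 for ENSRNOG00000043451 and -1.40 for ENSRNOG00000010932. It was 2.64 for ENSRNOG00000019481 and 2.59 for ENSRNOG00000002602, which fell in medulla (-4.61 and -4.06) and did not pass the expression filter of the cortex fit. Both interactions were smaller in size than the medulla falls, so both IDs were also lower in obese than in lean cortex. The log2 scale used understates changes at such low levels, so a fall confined to medulla was not shown. With MK-8722 10 mpk the log2 effect in cortex minus that in medulla was 2.17 for ENSRNOG00000011269, which did not pass the expression filter of the medulla fit, and -2.03 for ENSRNOG00000009589.

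Most obesity calls were rises. Without the 6 most abundant gene IDs, and with libraries brought to 1 sum, the median log2 fold change went from 0.304 to 0.174 in cortex (0.163 to 0.191 leaving out single libraries) and from 0.372 to 0.231 in medulla (0.216 to 0.242), so these genes may account for part of the shift and not all of it. The slope of library medians on depth within groups predicts a shift of 0.0777 in medulla (at most 0.165 within 2 SE) against 0.397 observed, which argues against depth as the main cause there. In cortex it predicts 0.126 (0.0583 to 0.194) against 0.36, which leaves depth open. Whether the remaining rise is a change per cell in obese kidneys was not tested.

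Enalapril libraries lay nearer to lean than obese vehicle libraries, while the difference for MK-8722 10 mpk did not pass. For enalapril, chance values of the shared vehicle libraries are argued against by the exact test (adjusted p = 0.0477 in cortex and 0.0476 in medulla); for MK-8722 10 mpk they stay open (0.166, or 0.0834 with the pairs kept, in cortex and 0.111 in medulla). With positions adjusted for depth within groups, the enalapril difference was -0.269 in medulla (-0.435 to -0.102, 2 SE), which argues against depth there, and -0.194 in cortex (-0.427 to 0.0386), which does not. For MK-8722 10 mpk the adjusted differences were -0.0483 in cortex (-0.304 to 0.208; -0.081 with the pairs in the fit, -0.374 to 0.212) and -0.146 in medulla (-0.337 to 0.0453), so depth and treatment cannot be told apart with these intervals. An effect of enalapril itself stays open as a hypothesis; the medulla calls with enalapril fell from 1509 to 7 without obese vehicle replicate 7.

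MK-8722 10 mpk and enalapril differed in cortex. With the number range as a term, 1074 of the 1308 calls were called again in the same direction, and after rescaling 1136 were. This argues against the range and the authors' scaling as the whole cause. In the lower range alone, with 2 MK-8722 10 mpk and 4 enalapril libraries, 230 genes were called, and leaving out as many libraries per group at random gave a median of 477.5 (160 to 1945, 3 of 30 draws at or below 230), so fewer libraries may account for this drop. In medulla, where no library is in the higher range, the cortex calls shifted in the cortex direction by 0.326 (exact p = 0.0159), and 92.7% of 1271 genes had the same sign. Different actions of the drugs may explain this, as a hypothesis; other differences between the animals were not tested.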

How the results depend on the processing

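Depth, number range and the results on the lean-to-obese line were chosen after the data were seen; the other alternatives were planned. Of 111 planned values other than single left-out libraries, 69 stayed within 1.5 times the count and 42 did not; a pseudocount of 0.1 moved no count beyond that. The cause was not tested. The list tests, with camera in place of fry, were not run for want of gene names. Depth limits low genes and is known only relative to other libraries.

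Rescaling gave 268 (enalapril), 1097 (MK-8722 10 mpk), 1324 (between doses), 251 and 649 (opposite calls) in cortex, and 582, 748, 400, 564 and 626 in medulla. Without the filter, enalapril gave 820 and its opposite calls 777 in cortex, and 755 and 724 in medulla. MK-8722 1 mpk gave 3, with 1 opposite call, in cortex, the enalapril interaction 2, and in medulla the drugs differed for 256 genes and the doses for 401. With only the 2 groups compared, counts were 312 (enalapril), 480 (MK-8722 10 mpk), 1966 (doses) and 796 (drugs) in cortex, and 973, 465, 72 and 48 in medulla.

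With the replicate number as a block, enalapril gave 4739 calls and 4464 opposite calls in cortex. In medulla the block gave 834 and 805 for enalapril, 1159 and 1049 for MK-8722 10 mpk, 105 between doses and 254 between drugs. The interactions became 338 (obesity, 125 more positive in cortex and 213 in medulla, against 428 and 281), 7 (MK-8722 10 mpk, 4 and 3) and 0 (enalapril); other counts, the paired cortex MK-8722 10 mpk among them, stayed within 1.5 times. With the block and depth together that pair gave 244 calls and 104 opposite calls, and with the block its position difference of -0.233 had an exact adjusted p of 0.0834. ENSRNOG00000003288 in medulla had an adjusted p of 0.0584 with the block. The labels give these libraries no link but a number, and in no comparison did every library correlate best with its own. Split obese vehicle libraries, which leave fewer of them to each comparison, gave 0.5 and 831 opposite calls in cortex and 2 and 512.5 in medulla.

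In the lower number range cortex gave 3778 (enalapril), 977 (MK-8722 10 mpk), 454 (doses) and 230 (drugs), with 3544 and 778 opposite calls, and a position difference for enalapril of -0.395, where fewer libraries limit the test. The range as a term gave 2183 (MK-8722 10 mpk), 2353 (doses) and 1480 (opposite). Depth as a term gave 4581 (obesity), 1 (enalapril), 431, 326 (doses), 1 and 150 (opposite) in cortex, 0 for the enalapril interaction, and 5451, 851, 455 and 641 (opposite calls of MK-8722 10 mpk) in medulla.

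Leaving out single libraries gave 23 to 4531 calls for enalapril, 1784 to 5188 for MK-8722 10 mpk, 1748 to 5215 between doses, and 18 to 4322 and 1091 to 4091 opposite calls in cortex. In medulla it gave 7 to 2345, 1030 to 3244, 150 to 1593, 5 to 2273 and 904 to 2932, 136 to 609 between drugs, and 0 to 1 for MK-8722 1 mpk. Interactions ranged over 446 to 911 (obesity), 0 to 2 (enalapril) and 18 to 59 (MK-8722 10 mpk). The cortex position difference for enalapril ranged from -0.408 to -0.288 and missed the adjusted threshold without any 1 of 8 libraries. Of 412 values for the 24 named ID comparisons, 0 changed sign and 33 missed the threshold, 30 of them with enalapril and none with obesity. The IDs were chosen for no overlap between the groups compared, so leaving out a library could not turn their sign.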

Other observations

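Genes enriched in one part of the kidney were defined after the data were seen, from the obese MK-8722 1 mpk libraries alone, with a log2 difference of at least 2 between the tissues; 59 were higher in cortex and 85 in medulla. The mean log2 level of the cortex genes minus that of the medulla genes, a balance that no library-wide scaling of high genes changes, was 4.26 ± 0.37 in lean and 4.12 ± 0.69 in obese vehicle cortex (SD, n = 5; exact permutation p = 0.714, adjusted over 6 tests 0.857). In medulla it was -0.485 ± 0.5 in lean and -0.939 ± 0.25 in obese vehicle libraries (exact permutation p = 0.0873, adjusted 0.524). With MK-8722 10 mpk it was -1.48 ± 0.89 in medulla, ranging from -2.45 to -0.428 (exact permutation p = 0.286 against obese vehicle, adjusted 0.548). Enalapril differed from obese vehicle by 0.404 in cortex and 0.273 in medulla, and neither difference passed (exact permutation p = 0.31 and 0.365, both adjusted 0.548). No difference in the balance passed the test, and the spread within the medulla groups was wide.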
